A study of Solanum lycopersicum with 9 samples.

How the data were processed

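RNA was measured in fruit peel of tomato (Solanum lycopersicum, cultivar Ailsa Craig) harvested at 55 days post anthesis. Per the labels, total RNA was extracted with Trizol, libraries were made with an Illumina mRNA kit, and sequencing used an Illumina HiSeq instrument. The lines nor, NOR-12 and NOR-M138Q-18 each had 3 libraries, and groups and replicate numbers were taken from the labels. What the constructs are was taken from the line names, the title of the series and general knowledge of NOR, and the column headers mark both transgene lines as OE. Whether replicates were separate plants, separate fruits or parts of one RNA is not given in the sources used here.

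The deposited table of all genes holds a read count and an FPKM value per gene and library, per the file headers. The counts are whole numbers with a different total in each library and are taken as raw counts made by the authors. FPKM was computed by the authors, with values rounded to 2 decimals, and its ratio to the count within a gene had a median spread of 0% over the 9 libraries across 8126 genes, once each library's total was taken into account. Per the labels, the authors' processing used Bowtie 0.12.2 and the build mm8. That build is of the mouse, whereas the identifiers are tomato gene models and assembled loci, so the tomato assembly, the annotation and the counting program are not given in the sources used here. Each of the authors' tables for a line against nor lists genes with a p-value and false discovery rate per gene, by a test that is not named. Their log2 fold change, per the file headers and checked on the values, is the log2 ratio of mean FPKM, with 0.001 in place of 0. Those tables hold only genes past a false discovery rate of 0.05 and a fold minimum, so they cannot show what was unchanged. No column of the table of all genes was left unmatched to a sample. Symbols in the table are often best hits in other species, so genes are named here by the names fixed in the lists or by identifier and description. A genome was not used here, so no coordinates are given.

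The table had 36234 entries, of which 35768 were gene models and 466 assembled loci. The library totals were 48717197, 50612214 and 39381168 counts in nor, 48587942, 44255629 and 38389525 in NOR-12, and 45545340, 44043938 and 38253002 in NOR-M138Q-18. The 10 genes with the highest counts took 4.5% to 6.1% of a library. The common biological coefficient of variation was 0.106. Floors of 3 counts over a group cover counting error only. No library repeated another: over genes with counts of at least 20, the chi-square per gene between libraries of a line lay between 5.13 and 19.4.

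Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr on the groups (20764 genes), libraries were scaled by TMM, and quasi-likelihood tests with robust dispersion were made in 1 fit of all 9 libraries. The comparisons were NOR-12 against nor, NOR-M138Q-18 against nor and, as the direct test of the difference, NOR-M138Q-18 against NOR-12. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05 and no fold minimum. All adjusted p-values for genes are two-sided and come from edgeR unless another tool is named. The groups, the comparisons, the tests, the gene lists and the alternatives were fixed before the data were examined. Fold changes are those of the fit, except that a gene with no count in a group is given as a bound. CPM uses the TMM-scaled library sizes. Independent overlap of calls was computed as the product of both counts over the number of genes. For the shared controls, 20 sets of unchanged lines, drawn around the nor means, were simulated against the same controls.

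The 27 gene lists were ripening regulators, ethylene synthesis, ethylene perception and response, carotenoid synthesis up to lycopene, carotenoid steps after lycopene, cell wall disassembly, chlorophyll breakdown, chloroplast development regulators, flavonoid synthesis, cuticle, aroma volatile synthesis, sugar, starch and acid metabolism, steroidal glycoalkaloid synthesis, light-harvesting proteins, photosystem subunits, Rubisco small subunits, methionine sulfoxide reductases, heat shock proteins, pathogenesis-related proteins, seed markers, vascular markers, core histones, cytosolic ribosomal proteins, expansins, lipoxygenases, auxin response factors with Aux/IAA proteins, and ethylene-responsive transcription factors. The first 13 were listed by identifier from general knowledge of tomato and the others by words in the gene description. Because the words decide membership, the pathogenesis-related list also holds the transcriptional activator PTI5, and the lipoxygenase list a lipoxygenase homology domain protein. Cuticle, seed, vascular and histone lists stand for epidermis, seed, vascular tissue and dividing cells, and all of these except seed occur in or near peel. Some genes are in more than 1 list, such as E4, EXP1, LOXC and EXPA5. A single member was removed before its values were seen, since its description names a vacuolar sorting protein, and LACS1, LACS2 and XYL2 follow the names in the table. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 27 lists, and again with the correlation estimated from the data. Of all list calls, photosystem subunits in the direct comparison alone held with an estimated correlation. The test fry of limma, also fixed beforehand, was run on each list, and no call here rests on it. In NOR-12 against nor its p-values, not adjusted over lists, were 3.38e-07 for light-harvesting genes and 2.64e-08 for photosystem subunits. Ripening regulators had a fry p of 1.22e-05 and core histones 0.114. Counts are given over all genes and adjusted over the list alone.

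Genes were named by a rule. It took NOR in each library and 27 anchor genes of ripening. In each comparison it added the 6 largest increases and 6 largest decreases among genes past the threshold with a mean of at least 5 CPM, no overlap between lines and a description that names a protein. Up to 4 members of each list with the smallest p were added. Photosynthesis sums, pathway tests and the simulation of both transgene lines at the NOR-12 means were chosen after the data were seen.

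The procedure was tested on data simulated around the nor means, with the spread and library sizes of the fit of all 9 libraries. Known changes were put into the NOR-12 libraries, in genes with a mean of at least 1 CPM. Of 67 genes changed 1.5-fold 68.7% were called, of 67 changed 2-fold 86.6%, and of 66 changed 4-fold 98.5%. Among 20294 genes 21 unchanged ones were called. The list test called the 1 raised list and none of 50 unchanged lists. Genes were simulated independently, so this check does not cover lists whose genes vary together.

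Alternatives were RLE factors, library sizes alone and upper-quartile factors in place of TMM; no filter beyond a single read; a filter of 1 CPM in 3 libraries; DESeq2 1.42.0; limma-voom; only the 6 libraries compared; replicate number as a block; a log2 fold minimum of 1; a threshold of 0.01; limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1); and each library left out in turn. No alternative was added later.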

Results

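The data were 9 RNA-seq libraries of tomato fruit peel, taken at 55 days post anthesis, with 3 libraries from each of the lines nor, NOR-12 and NOR-M138Q-18. The nor line carries the ripening mutation of the NAC transcription factor NOR, and the title of the series concerns sulfoxidation of NOR. From their names, the other lines carry transgenes for NOR itself and for NOR with the substitution M138Q, in which glutamine takes the place of methionine. Glutamine is often used as a stand-in for methionine sulfoxide. Each construct was represented by a single line, so a difference between lines could not be separated from a difference between insertions of the transgene.

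Transcripts counted on the NOR gene were abundant in all 9 libraries, with means (± SD, n = 3 libraries per line, as for every mean that follows) of 870.1 ± 48.9 CPM (counts scaled by library size) in nor, 807 ± 15.2 in NOR-12 and 832 ± 10.7 in NOR-M138Q-18. The libraries held 893, 903 and 814 CPM in nor, 809, 792 and 822 in NOR-12, and 835, 820.2 and 841 in NOR-M138Q-18. In NOR-12 against nor the log2 difference was -0.11 with an adjusted p of 0.0369, and leaving out any library except nor replicate 3 ended that call, with adjusted p values between 0.0536 and 0.146, as did the replicate block (0.0559; range over all alternatives 0.000697 to 0.146). The log2 difference for NOR-M138Q-18 against nor was -0.06 with an adjusted p of 0.241. It passed the test with library sizes alone (0.0068), with upper-quartile scaling (0.00391), on FPKM (0.0127 and 0.0126) and without nor replicate 3 (0.0137; range over all alternatives 0.00391 to 0.563). Counts per gene do not separate transcripts of the mutant gene from those of a transgene, so these values do not show how much of each was made and do not check the labels of the lines.

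The lines were well separated. The first principal component, with 51.2% of the variance, placed nor between -81.8 and -80.0, NOR-M138Q-18 between 18 and 19.2 and NOR-12 between 54.7 and 69.2. The second, with 22.1%, set NOR-M138Q-18 (-55.8 to -52.9) apart from nor (15.3 to 17.7) and NOR-12 (30.2 to 42.3). Correlations of log2 CPM across genes were 0.982 to 0.985 within lines and 0.922 to 0.965 between them. The origin of the replicates is not given in the sources used here, so every p-value measures only the spread between these samples, which may be technical.

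NOR-12 peel had more transcript of several ethylene and ripening genes than nor peel and less of photosynthesis genes. Transcripts of ACS2, an enzyme that makes the ethylene precursor ACC, stood at 19.0 ± 1.68 CPM in nor and 134 ± 9.32 CPM in NOR-12, a 7.07-fold rise (adjusted p = 2.54e-14). ACO1, which turns ACC into ethylene, rose 4.1-fold from 388 ± 33.5 to 1588 ± 48.9 CPM, and the ethylene-induced ripening gene E8 rose 3.05-fold from 1356 ± 33.0 to 4135 ± 223 CPM. The polygalacturonase PG2A, which cuts pectin in ripening fruit, rose 4.18-fold from 42.0 ± 2.20 to 175 ± 7.87 CPM. Of 20 genes for chlorophyll-binding proteins 17 fell, of 34 for photosystem subunits 26 fell and 2 rose, and all 3 for Rubisco small subunits fell, with log2 medians of -1.98, -1.40 and -2.81. The calls of these lists ended with an estimated correlation (adjusted p of 0.133, 0.0748 and 0.255).

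Of 12 measured ethylene synthesis genes, 8 rose, 3 fell and 1 did not pass the test in NOR-12 (adjusted p of the list = 0.000337; adjusted p = 0.133 with an estimated correlation). ACO5 rose 6.68-fold to 97.9 ± 6.05 CPM and ACO3 2.05-fold to 34.3 ± 0.911 CPM, while ACS4 fell from 251 ± 15.3 to 177 ± 7.43 CPM and ACO6 from 861 ± 92.6 to 82.9 ± 34.1 CPM. The list's call ended with limma-voom and on FPKM (adjusted p of 0.0781, 0.0775 and 0.069; range over all alternatives 5.4e-05 to 0.0781). Among 19 genes of ethylene perception and response, 13 rose and 5 fell, with 1 not past the threshold (adjusted p of the list = 0.0587). With upper-quartile scaling 8 rose and 5 fell. This list passed with no filter (0.0408), with DESeq2 (0.025) and without NOR-12 replicate 3 (0.0443; range over all alternatives 0.025 to 0.105). Its members included the receptors NR (1.58-fold higher) and ETR4 (1.94-fold higher), the F-box protein EBF2, which acts in ethylene signalling (1.64-fold higher), and E4, itself a peptide methionine sulfoxide reductase (1.59-fold higher, 397 ± 8.68 to 629.7 ± 21.0 CPM). Ethylene-responsive transcription factors had 31 of 64 members higher and 17 lower (adjusted p of the list = 0.0429; adjusted p = 0.618 with an estimated correlation). Examples were ERF4 (Solyc07g053740.1, 159 ± 10.2 to 439 ± 15.7 CPM) and ERF014 (Solyc11g012980.1, 17.9 ± 1.96 to 80.2 ± 1.14 CPM). The call of this last list ended with DESeq2 (0.0557), with limma-voom (0.124), with 6 libraries (0.0606), with the replicate block (0.0624), on FPKM (0.0929 and 0.0893), without nor replicate 3 (0.067) and without NOR-M138Q-18 replicate 1 (0.0522), within a range of 0.019 to 0.124 over all alternatives.

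Ripening regulators went both ways in NOR-12: 7 of 13 rose, 3 fell and 3 did not pass the test (adjusted p of the list = 0.0587). The 3 that fell include NOR itself, whose counts do not separate the mutant gene from a transgene and whose call was not stable. The list passed with no filter (0.0408), with DESeq2 (0.04) and without nor replicate 1 (0.0314) or NOR-12 replicate 3 (0.049; range over all alternatives 0.0314 to 0.182). The MADS-box regulator RIN rose from 314 ± 29.1 to 554 ± 13.03 CPM (1.76-fold, adjusted p = 3.44e-09) and FUL1 from 145 ± 6.80 to 425 ± 11.4 CPM (2.93-fold). DML2, a DNA demethylase active in ripening, rose 1.9-fold and CNR 1.25-fold, while TAGL1 stood at 134 ± 5.69 and 134 ± 1.77 CPM (adjusted p = 0.908). Of 10 genes leading to lycopene, 4 rose and 3 fell (adjusted p of the list = 0.754), and with upper-quartile scaling these counts became 4 and 5. Phytoene synthase PSY1 rose 1.34-fold from 2596 ± 161 to 3470 ± 76.8 CPM and Z-ISO 2.11-fold to 897 ± 42.1 CPM, whereas PDS fell from 161 ± 4.33 to 125 ± 1.39 CPM. Among 13 genes after lycopene 4 rose and 6 fell (adjusted p of the list = 0.391). The cyclase gene LCY-E, at 1.76 ± 0.157 CPM in nor, had no count in any NOR-12 library, which makes it at least 77.4-fold lower against a floor of 3 counts over the group. The hydroxylase genes BCH1 and BCH2 rose 2.45-fold and 2.28-fold.

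The decrease of photosynthesis genes in NOR-12 covered 17 of 20 light-harvesting genes, with none higher (adjusted p of the list = 3.35e-10; adjusted p = 0.133 with an estimated correlation). Photosystem subunits had 26 of 34 members lower and 2 higher (adjusted p of the list = 8.53e-12; adjusted p = 0.0748 with an estimated correlation), and all 3 Rubisco small subunit genes were lower (adjusted p of the list = 0.00254; adjusted p = 0.255 with an estimated correlation). The Rubisco call ended on log2(FPKM + 0.1) with an adjusted p of 0.0521 (range 5.93e-05 to 0.0521), and the gene Solyc02g085950.3, at 1.06 ± 0.189 CPM in nor, lost its own call with the replicate block (0.0579) and without nor replicate 1 (0.137), 2 (0.0513) or 3 (0.0591), NOR-12 replicate 2 (0.124) or 3 (0.127), or NOR-M138Q-18 replicate 2 (0.0507; range of adjusted p over all alternatives 0.00859 to 0.137). Solyc05g056070.3, for the chlorophyll-binding protein 6A, fell from 53.8 ± 5.45 to 7.57 ± 1.51 CPM. Solyc02g079950.3, for an oxygen-evolving protein of photosystem II, fell from 169 ± 5.21 to 49.6 ± 3.68 CPM, and the Rubisco gene Solyc03g034220.3 fell from 113 ± 4.45 to 16.0 ± 3.05 CPM. GLK2, a transcription factor that promotes chloroplast development in fruit, fell from 7.99 ± 0.844 to 2.15 ± 0.333 CPM. With GLK1 also lower and APRR2-like higher, the list of chloroplast regulators had an adjusted p of 0.453. Among 5 chlorophyll breakdown genes 1 rose and 2 fell (adjusted p of the list = 0.576), and SGR1, the stay-green protein, stood at 169.9 ± 27.0 and 179 ± 2.60 CPM (adjusted p = 0.538); without nor replicate 1 its log2 difference of 0.07 became 0.19 and passed the test.

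Cell wall genes were split in NOR-12, with 6 of 17 higher and 8 lower (adjusted p of the list = 0.46). PG2A, the pectate lyase PL (1.47-fold) and the expansin EXP1 (270.2 ± 18.5 to 399 ± 17.9 CPM) rose, while the pectin methylesterase PE1 fell from 2698 ± 39.7 to 914 ± 59.4 CPM and the galactosidase TBG6 from 147 ± 0.871 to 72.8 ± 5.54 CPM. Expansins as a family had 4 of 12 higher and 5 lower (adjusted p of the list = 0.633). Aroma genes had 7 of 10 higher and 2 lower (adjusted p of the list = 0.0744). That list passed with no filter (0.0408) and without nor replicate 1 (0.0371) or NOR-12 replicate 3 (0.049; range over all alternatives 0.0371 to 0.182). Among them were AADC1A, a decarboxylase of phenylalanine-derived volatiles (2.66 ± 0.575 to 65.0 ± 3.59 CPM, 24.5-fold), and LOXC (1.39-fold). Lipoxygenases had 8 of 12 higher and 3 lower (adjusted p of the list = 0.107), passing without nor replicate 1 (0.0371; range over all alternatives 0.0371 to 0.508). Sugar, starch and acid genes were mostly lower, 7 of 12 against 3 higher (adjusted p of the list = 0.0204; adjusted p = 0.152 with an estimated correlation), and that call ended with limma-voom (0.0901) and on FPKM (0.134 and 0.14; range over all alternatives 0.00687 to 0.14). AGPS1, of starch synthesis, fell from 148 ± 2.70 to 49.0 ± 4.44 CPM and GAD1, a glutamate decarboxylase, from 550.1 ± 11.9 to 256 ± 9.47 CPM.

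Further groups in NOR-12 moved in both directions. Methionine sulfoxide reductases, enzymes that reverse methionine oxidation, had 5 members higher and 5 lower (adjusted p of the list = 0.316), and the list's median of 0.06 became -0.03 with upper-quartile scaling. MSRB5 (Solyc01g080410.3) rose from 10.5 ± 0.432 to 44.3 ± 3.40 CPM and Solyc02g063250.3 from 9.60 ± 1.92 to 42.0 ± 1.21 CPM, while MSRA4 (Solyc03g093690.3) fell from 172 ± 4.96 to 127 ± 2.14 CPM. Heat shock proteins had 20 of 52 members higher and 17 lower (adjusted p of the list = 0.685), which became 16 higher and 17 lower with upper-quartile scaling. Pathogenesis-related proteins and chitinases had 13 of 36 higher and 11 lower (adjusted p of the list = 0.132), with the PR protein P2 (Solyc01g097240.3) rising from 80.4 ± 4.69 to 327 ± 7.15 CPM. Glycoalkaloid genes had 2 of 9 higher and 4 lower (0.46), flavonoid genes 2 of 8 and 3 (0.453), auxin response factors and Aux/IAA proteins 7 of 27 and 9 (0.754), and ribosomal proteins 91 of 172 and 19 (0.316), each with the adjusted p of its list. With upper-quartile scaling 6 auxin response genes were higher and 14 lower, 1 flavonoid gene was higher and 4 lower, and 63 ribosomal protein genes were higher and 31 lower. The ribosomal list passed with limma-voom (0.00207) and on FPKM (0.0264 and 0.0236; range over all alternatives 0.00207 to 0.563).

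Marker lists of particular cells or tissues were read beside these groups. In NOR-12 cuticle genes, markers of the epidermis, had 1 of 15 members higher and 7 lower (adjusted p of the list = 0.14), with CYP77A2 at 25.9 ± 1.57 and 11.6 ± 0.986 CPM and CER3 rising 1.54-fold. Seed storage proteins and oleosins had 3 of 7 higher and 2 lower (0.685), lignin and secondary wall genes 3 of 10 higher and none lower (0.741), and core histones 3 of 30 higher and 7 lower (0.46), each with the adjusted p of its list. The most raised seed gene by the named-gene rule, the legumin-like Solyc03g005580.2, reached only 1.95 ± 0.568 CPM in NOR-12 from 0 in nor, at least 91.2-fold higher against the floor of 3 counts over the group.

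The largest increases in NOR-12 among described genes with a mean of at least 5 CPM over the 9 libraries were in the beta-xylosidase gene XYL2 (0.376 ± 0.259 to 35.1 ± 1.16 CPM, 88.3-fold), the nudix hydrolase Solyc01g005390.3 (87.6-fold) and Solyc01g109120.3, described as similar to a myosin heavy chain kinase (51.9-fold). They were followed by the zinc finger protein Solyc06g075780.2 (31.1-fold), the NDR1/HIN1-like Solyc10g081970.2 (30.1-fold) and the calcium-binding protein Solyc04g058170.1 (26.4-fold). Among the same genes the largest decrease was in Solyc01g111075.1, for the antimicrobial peptide precursor snakin-2, from 622 ± 15.8 to 0.347 ± 0.113 CPM (1770-fold). Glycolate oxidase Solyc10g007600.3, of photorespiration, fell 21.4-fold to 30.8 ± 25.4 CPM, and its log2 change of -4.42 became -5.36 without NOR-12 replicate 1. That of Solyc01g005390.3, 6.45, became 7.78 without nor replicate 1. The 9-lipoxygenase A gene Solyc08g014000.3 fell 10.5-fold. The beta-galactosidase Solyc01g110000.3 fell 13.1-fold, the RALF-like peptide Solyc02g065780.1 fell 10.6-fold and ACO6 fell 10.4-fold.

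By the edgeR test 11443 of 20764 genes (55.1%) differed between NOR-12 and nor, 6089 higher and 5354 lower, and 3691 of them by at least 2-fold (2041 higher, 1650 lower). The values of the lines did not overlap for 61.2% of genes, where chance gives 10%. With upper-quartile scaling the share of higher genes moved from 53.2% to 41.7%. Adjusted over the list alone, the list counts for this comparison were the same except for 8 higher and 4 lower in ethylene synthesis, 14 and 5 in ethylene perception and response, 5 and 3 up to lycopene, 4 and 7 after lycopene, 6 and 9 in cell wall genes, 0 and 18 in light-harvesting genes, 21 and 17 in heat shock proteins and 32 and 19 in ethylene-responsive factors. Signs differed for seed markers (median -0.01, mean 1.07, test upward), expansins (median -0.20, mean -0.01, test upward) and auxin response genes (median -0.10, mean 0.13, test downward).

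**Figure D1:**
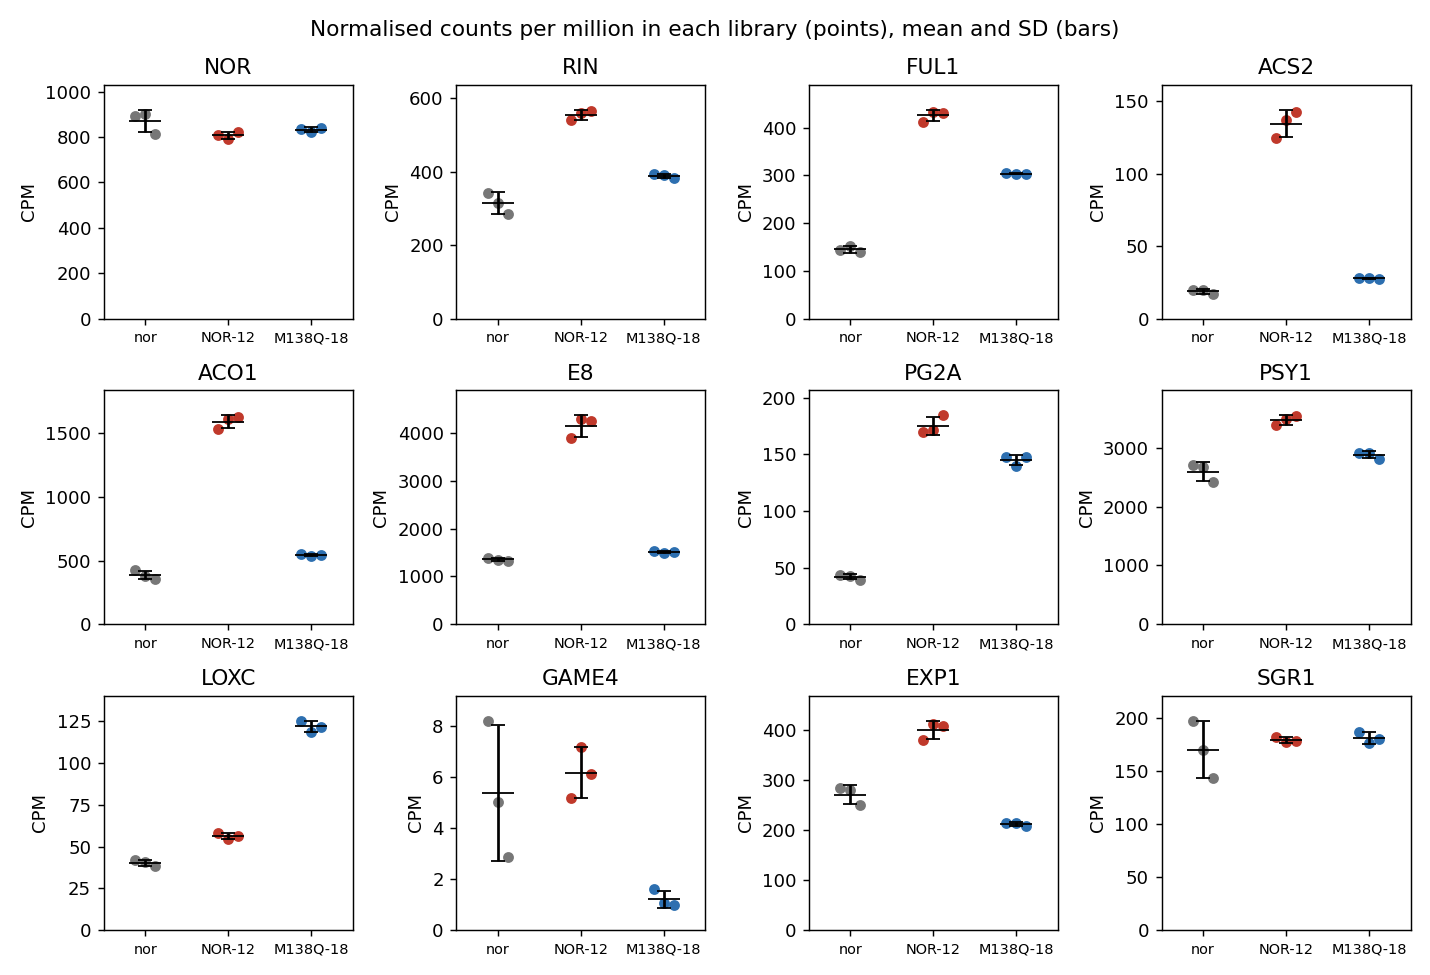
Normalised CPM (counts scaled by library size) of ripening marker genes in the 9 libraries; points are libraries, bars are the mean of the 3 libraries of a line and error bars their SD. ACS2 and E8 are higher in NOR-12 than in the other lines (134 and 4135 CPM), while PG2A is high in both transgene lines (175 and 145 CPM).

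Several ripening genes were higher in NOR-M138Q-18 peel than in nor peel. PG2A rose 3.46-fold, from 42.0 ± 2.20 to 145 ± 4.52 CPM (adjusted p = 1.09e-13), and FUL1 2.09-fold to 303 ± 1.53 CPM. LOXC, a lipoxygenase of fruit aroma, rose 3.02-fold from 40.3 ± 1.84 to 122 ± 3.22 CPM. ACS2 and ACO1 rose 1.46-fold and 1.4-fold, to 27.8 ± 0.602 and 544 ± 7.18 CPM. Of 52 heat shock genes 27 were higher and 3 lower, and of 9 glycoalkaloid genes 1 was higher and 8 were lower. The calls of both lists ended with an estimated correlation (adjusted p = 0.444 for each). The heat shock counts became 21 higher and 10 lower with library sizes alone and 21 and 11 with upper-quartile scaling.

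Ripening regulators in NOR-M138Q-18 had 6 of 13 members higher and 5 lower (adjusted p of the list = 0.933), which became 5 and 7 with library sizes alone and with upper-quartile scaling. RIN rose 1.24-fold to 389 ± 5.66 CPM and CNR 1.49-fold to 474 ± 18.6 CPM. LOB1, a regulator of wall genes, fell from 71.9 ± 7.30 to 39.6 ± 0.733 CPM, and NOR-like1 from 239 ± 28.9 to 130.4 ± 2.52 CPM. TAGL1 lay at 124 ± 3.55 CPM, with an adjusted p of 0.043, a call that ended with 6 libraries (0.063), with the replicate block (0.0667) and without any single library except nor replicate 3 (0.0559 to 0.178; range over all alternatives 0.000536 to 0.178). Ethylene synthesis had 7 of 12 members higher and 2 lower (adjusted p of the list = 0.0588). The list passed with no filter (0.0379), on FPKM (0.0482 and 0.0437) and without NOR-M138Q-18 replicate 1 (0.0359; range over all alternatives 0.0359 to 0.188). With library sizes alone and with upper-quartile scaling 7 were higher and 4 lower. Among them ACS1A rose from 8.85 ± 0.853 to 30.9 ± 1.49 CPM, SAMS2 1.92-fold and ACO5 2.95-fold, and ACS4 fell 1.69-fold. Ethylene perception and response had 8 of 19 higher and 4 lower (adjusted p of the list = 0.909), which became 6 and 6 with library sizes alone and with upper-quartile scaling. NR rose 1.24-fold, EBF1 rose 1.48-fold, EBF2 fell 1.44-fold, and E4 stood at 417 ± 21.7 CPM (adjusted p = 0.21). E8 lay 1.11-fold higher (adjusted p = 0.00609), a call that ended with library sizes alone, with upper-quartile scaling and on FPKM (range over all alternatives 0.00109 to 0.295). Ethylene-responsive factors had 33 of 64 members higher and 13 lower (adjusted p of the list = 0.0088; adjusted p = 0.444 with an estimated correlation), with Solyc07g053740.1 (ERF4) rising 2.91-fold. These counts became 30 higher and 20 lower with library sizes alone and with upper-quartile scaling.

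Genes leading to lycopene had 6 of 10 members higher and 1 lower in NOR-M138Q-18 (adjusted p of the list = 0.293; 0.0332 with limma-voom, range over all alternatives 0.0332 to 0.532). Z-ISO rose 1.9-fold to 809 ± 5.97 CPM and CRTISO, which isomerises prolycopene, 1.27-fold to 233 ± 2.74 CPM. PSY1 lay 1.11-fold higher (adjusted p = 0.0107), which did not hold with library sizes alone, with upper-quartile scaling or on FPKM (range over all alternatives 0.00124 to 0.379). Genes after lycopene had 5 of 13 higher and 4 lower (adjusted p of the list = 0.933), with NCED1, of abscisic acid synthesis, rising from 128 ± 5.66 to 215 ± 5.73 CPM and LCY-E falling 4.36-fold. Light-harvesting genes had 16 of 20 lower and 1 higher (adjusted p of the list = 0.00289; adjusted p = 0.444 with an estimated correlation), with Solyc05g056070.3 at 25.1 ± 0.862 CPM. Photosystem subunits had 14 of 34 lower and 3 higher (adjusted p of the list = 0.154), Rubisco small subunits 1 of 3 lower (0.293) and chlorophyll breakdown genes 2 of 5 lower (0.741). The photosystem list passed with limma-voom (0.0292) and on log2(FPKM + 1) (0.0482; range over all alternatives 0.0292 to 0.232), and its counts became 1 higher and 15 lower with upper-quartile scaling. With library sizes alone and with upper-quartile scaling 2 of 3 Rubisco genes and 16 of 20 light-harvesting genes were lower and none higher. The Rubisco gene Solyc03g034220.3 passed the test as lower with these scalings (0.0232 and 0.0203), DESeq2 (0.0242), limma-voom (0.00838), 6 libraries (0.00215), the replicate block (0.0254) and FPKM (0.0285 and 0.0355). It also passed without NOR-12 replicate 1 (0.00263) or 2 (0.0239; range over all alternatives 0.00215 to 0.255). None of the 3 chloroplast regulators passed the test (adjusted p of the list = 0.909), and GLK2 stood at 7.84 ± 0.772 CPM. GLK1 passed as lower with limma-trend on log2(FPKM + 1) (adjusted p = 0.0495, range over all alternatives 0.0495 to 0.566).

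Glycoalkaloid synthesis genes, which make the bitter steroidal alkaloids of green fruit, had 8 of 9 members lower and 1 higher in NOR-M138Q-18 (median log2 -2.09, adjusted p of the list = 0.00135; adjusted p = 0.444 with an estimated correlation). GAME12 fell from 26.3 ± 5.54 to 5.28 ± 0.485 CPM, GAME25 from 38.4 ± 4.60 to 10.95 ± 1.79 CPM and GAME4 from 5.36 ± 2.67 to 1.21 ± 0.336 CPM. Heat shock proteins had 27 of 52 members higher and 3 lower (adjusted p of the list = 0.00135; adjusted p = 0.444 with an estimated correlation). The cognate 70 kDa protein gene Solyc06g076020.3 rose 8.53-fold from 27.4 ± 2.66 to 233 ± 2.22 CPM and HSP70-3 (Solyc04g011440.4) 2.86-fold to 1052 ± 14.2 CPM. Methionine sulfoxide reductases had 4 of 10 members higher and none lower (adjusted p of the list = 0.535), counts that became 2 higher and 1 lower with library sizes alone and with upper-quartile scaling. MSRB5 (Solyc01g080410.3) rose 2.37-fold and Solyc02g083360.1, for an MsrB enzyme, rose from 7.37 ± 0.769 to 15.6 ± 0.690 CPM. Pathogenesis-related genes had 8 of 36 higher and 13 lower (adjusted p of the list = 0.933), with the activator PTI5 (Solyc02g077370.1) rising from 1.83 ± 0.216 to 17.9 ± 1.25 CPM.

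Aroma genes had 6 of 10 members higher and none lower in NOR-M138Q-18 (adjusted p of the list = 0.00289; adjusted p = 0.444 with an estimated correlation), a call that ended on log2(FPKM + 0.1) with 0.0554 (range over all alternatives 0.000493 to 0.0554). These counts became 5 higher and 3 lower with library sizes alone and 4 and 3 with upper-quartile scaling. AADC1A rose 20.5-fold to 54.5 ± 1.21 CPM. Lipoxygenases had 6 of 12 higher and 2 lower (adjusted p of the list = 0.00963; adjusted p = 0.371 with an estimated correlation), ending with limma-voom (0.0548) and with 6 libraries (0.126; range over all alternatives 0.00106 to 0.126). The 13-lipoxygenase gene Solyc03g122340.3 rose from 47.4 ± 6.87 to 617 ± 12.6 CPM. Expansins had 5 of 12 higher and 1 lower (adjusted p of the list = 0.0293; adjusted p = 0.415 with an estimated correlation), with Solyc01g112000.3 rising 6.62-fold and EXP1 falling 1.28-fold. With library sizes alone and with upper-quartile scaling 2 expansins were lower. The expansin call ended with no filter (0.146), with limma-voom (0.209), on FPKM (0.103 and 0.13), and without nor replicate 1 (0.121) or 2 (0.0729), NOR-12 replicate 1 (0.0676) or NOR-M138Q-18 replicate 1 (0.057), 2 (0.0636) or 3 (0.055), within a range of 0.0199 to 0.209. Sugar, starch and acid genes had 8 of 12 lower and none higher (adjusted p of the list = 0.0211; adjusted p = 0.371 with an estimated correlation), among them AGPS1 at 97.4 ± 3.68 CPM and the invertase inhibitor INVINH1, which fell 3.02-fold. Cell wall genes had 7 of 17 higher and 8 lower (adjusted p of the list = 0.749), and flavonoid genes 4 of 8 higher and 3 lower (0.933).

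Of the marker lists, cuticle genes had 5 of 15 members higher and 6 lower in NOR-M138Q-18 (adjusted p of the list = 0.741), with CER3 1.89-fold higher. Seed markers had 3 of 7 higher (0.677), vascular markers 2 of 10 higher and 1 lower (0.933), core histones 1 of 30 higher and 10 lower (0.203), ribosomal proteins 5 of 172 higher and 33 lower (0.0805) and auxin response genes 7 of 27 higher and 6 lower (0.933), each with the adjusted p of its list. The auxin response counts became 5 higher and 10 lower with library sizes alone. Ribosomal protein counts became 1 higher and 96 lower with library sizes alone and 1 and 103 with upper-quartile scaling. Their list passed under both (0.012 and 0.00963), with limma-voom (0.0292), on FPKM (0.000956 and 0.00102) and without nor replicate 2 (0.0407; range over all alternatives 0.000956 to 0.204). With an estimated correlation its adjusted p was 0.827. The histone list passed on log2(FPKM + 1) (0.0482; range over all alternatives 0.0482 to 0.336). The largest increases among described genes with a mean of at least 5 CPM over the 9 libraries were in the assembled locus MSTRG.15563 (44.3-fold), Solyc01g005390.3 (35.5-fold), pectinesterase 3 (Solyc03g123620.4, 12.6 ± 0.913 to 432 ± 4.76 CPM, 34.3-fold), the calcium ATPase Solyc09g082870.2 (33.1-fold), bHLH92 (Solyc09g083360.3, 23-fold) and Solyc04g058170.1 (21.9-fold). The log2 change of Solyc01g005390.3, 5.15, became 6.48 without nor replicate 1. Within the same limits the largest decreases were in the ubiquitin ligase gene Solyc00g136260.1 (7.54-fold), the retrovirus-related locus MSTRG.702 (7.19-fold), Solyc05g050830.2, for an ERF038-like factor (6.17-fold), the pectinesterase Solyc06g009190.3 (4.96-fold), the receptor-like kinase Solyc02g071800.3 (4.76-fold) and the BTB/POZ protein Solyc09g074630.3 (4.56-fold).

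By the edgeR test 8210 genes (39.5%) differed between NOR-M138Q-18 and nor, 4364 higher and 3846 lower. Of these, 2477 differed by at least 2-fold, 1759 higher (71.0%) and 718 lower. For 49.3% of genes the values of the lines did not overlap (10% by chance). The share of higher genes among all called, 53.2%, fell to 37.0% with library sizes alone, 35.4% with upper-quartile scaling and 36.9% and 37.4% on FPKM, and upper-quartile scaling moved the median log2 change of all genes from -0.01 to -0.11. Adjusted over the list alone, the list counts were the same except for 6 higher and 6 lower ripening regulators, 7 and 3 in ethylene synthesis, 9 and 4 in ethylene perception and response, 6 and 1 aroma genes, 1 and 17 light-harvesting genes, 4 and 0 seed markers, 1 and 9 histones, 3 and 19 ribosomal proteins, 7 and 2 lipoxygenases, 7 and 7 auxin response genes and 35 and 18 ethylene-responsive factors. Signs differed for ripening regulators (median -0.06, mean 0.03, test upward), genes after lycopene (median 0.00, mean -0.26, test downward), cell wall genes (median -0.26, mean 0.04, test downward), vascular markers (median 0.31, mean 0.17, test downward) and auxin response genes (median 0.05, mean 0.15, test downward).

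Tested directly, NOR-M138Q-18 peel had less transcript of the ethylene-related genes ACS2, ACO1 and E8 than NOR-12 peel and more of photosystem genes. ACS2 was 4.83-fold lower (27.8 ± 0.602 against 134 ± 9.32 CPM, adjusted p = 1.99e-12), ACO1 2.92-fold lower and E8 2.74-fold lower. RIN and FUL1 were 1.43-fold and 1.4-fold lower, and PG2A was 1.21-fold lower. Photosystem subunits had 26 of 34 members higher and none lower, with a log2 median of 1.11. GLK2 was 3.64-fold higher, at 7.84 ± 0.772 CPM beside 7.99 ± 0.844 CPM in nor.

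Photosystem subunits gave an adjusted p of 1.37e-18 for the list, and this was the only call among the 27 lists and 3 comparisons that held with an estimated correlation (adjusted p = 0.0228). Light-harvesting genes had 14 of 20 members higher and none lower (adjusted p of the list = 2.48e-08; adjusted p = 0.201 with an estimated correlation). Of the Rubisco small subunit genes 2 of 3 were higher (adjusted p of the list = 0.000408; adjusted p = 0.201 with an estimated correlation), a call that ended with limma-voom (0.0535; range over all alternatives 5.82e-07 to 0.0535). Solyc03g034220.3 stood at 96.1 ± 3.31 CPM in NOR-M138Q-18 against 16.0 ± 3.05 in NOR-12. Summed over the 55 measured members of these groups, photosynthesis transcripts reached 3367, 3212 and 3275 CPM in nor, 2559, 2530 and 2517 in NOR-M138Q-18, and 1242, 1122 and 1100 in NOR-12. The chloroplast regulators GLK1 and GLK2 were higher and APRR2-like lower (adjusted p of the list = 0.35). Chlorophyll breakdown genes had 2 of 5 members higher and 1 lower (adjusted p of the list = 0.853), and their median of 0.02 became -0.03 with library sizes alone.

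Ripening regulators had 8 of 13 members lower and 3 higher in the direct test (adjusted p of the list = 0.00121; adjusted p = 0.274 with an estimated correlation), with AP2a, DML2 and NAC4 lower by 1.87-fold, 1.69-fold and 1.73-fold and CNR higher by 1.19-fold. The call ended on log2(FPKM + 0.1) with 0.0505 (range over all alternatives 0.000355 to 0.0505). Ethylene synthesis had 6 of 12 lower and 3 higher (adjusted p of the list = 0.00185; adjusted p = 0.201 with an estimated correlation), ending with limma-voom (0.333), with 6 libraries (0.0674), on FPKM (0.48 and 0.464) and without NOR-12 replicate 1 (0.0807), within a range of 0.000545 to 0.48. Ethylene perception and response had 8 of 19 lower and 5 higher (adjusted p of the list = 0.00258; adjusted p = 0.344 with an estimated correlation), ending with limma-voom (0.148), with 6 libraries (0.0677) and on FPKM (0.174 and 0.166; range over all alternatives 0.000555 to 0.174). EBF2 was 2.37-fold lower, ETR4 1.61-fold lower and E4 1.51-fold lower. Ethylene-responsive factors had 20 of 64 members higher and 11 lower (adjusted p of the list = 0.804).

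Glycoalkaloid genes had 7 of 9 members lower and none higher in NOR-M138Q-18 than in NOR-12 (adjusted p of the list = 0.000378; adjusted p = 0.344 with an estimated correlation), with GAME18 4.61-fold, GAME4 5.06-fold and GAME12 2.51-fold lower. Heat shock proteins had 26 of 52 higher and 8 lower (adjusted p of the list = 1.05e-05, or 0.241 with an estimated correlation). The chloroplast small heat shock protein gene Solyc03g082420.3 stood at 84.6 ± 4.74 CPM in NOR-M138Q-18 against 26.8 ± 2.23 CPM in NOR-12. The cognate protein 80 gene Solyc07g065840.2 stood at 4974 ± 13.9 against 2755 ± 102 CPM, in the same order. Cytosolic ribosomal proteins had 115 of 172 lower and 12 higher, by a median log2 of -0.19 (adjusted p of the list = 1.22e-06; adjusted p = 0.344 with an estimated correlation). Expansins had 6 of 12 higher and 1 lower (adjusted p of the list = 0.0108; adjusted p = 0.201 with an estimated correlation), ending with no filter (0.165) and without nor replicate 1 (0.0681; range over all alternatives 0.00529 to 0.165). EXPA5 was 3.44-fold higher and EXP1 1.89-fold lower. Pathogenesis-related genes had 12 of 36 lower and 5 higher (adjusted p of the list = 0.00281; adjusted p = 0.237 with an estimated correlation), ending with limma-voom (0.163) and on FPKM (0.326 and 0.359; range over all alternatives 0.00146 to 0.359). The acidic endochitinase gene Solyc05g050130.3 stood at 15.1 ± 1.32 CPM in NOR-M138Q-18 against 77.3 ± 1.63 CPM in NOR-12.

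No other list passed the direct test. Cuticle genes had 9 of 15 members higher and none lower (adjusted p of the list = 0.0972), and this list passed with limma-voom (0.0255) and on FPKM (0.02 and 0.0224; range over all alternatives 0.02 to 0.278). Genes up to lycopene had 5 of 10 higher and 3 lower (0.254), genes after lycopene 5 of 13 and 1 (0.125), cell wall genes 8 of 17 and 7 (0.778), flavonoid genes 4 of 8 and 0 (0.13), aroma genes 2 of 10 and 2 (0.308), sugar genes 4 of 12 and 3 (0.531), and lipoxygenases 6 of 12 and 4 (0.278), each with the adjusted p of its list. The lipoxygenase list passed without NOR-12 replicate 1 (0.0467; range over all alternatives 0.0467 to 0.372). Within these, LOXC was 2.17-fold higher in NOR-M138Q-18, NCED1 1.8-fold higher, HPL 1.8-fold higher and PSY1 1.2-fold lower. Methionine sulfoxide reductases had 4 of 10 higher and 4 lower (0.531), seed markers 2 of 7 and 1 (0.853), vascular markers 1 of 10 and 2 (0.531), histones 4 of 30 and 6 (0.531), and auxin response genes 5 of 27 and 5 (0.966). With library sizes alone histones had 1 higher and 7 lower, vascular markers 1 and 4, flavonoid genes 3 and 1, genes after lycopene 5 and 2, chlorophyll breakdown genes 1 and 1 and photosystem subunits 26 and 1. The median of aroma genes turned from 0.02 to -0.03 and that of auxin response genes from 0.03 to -0.02 under another scaling.

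Among described genes with a mean of at least 5 CPM over the 9 libraries, the largest direct differences were higher snakin-2 (Solyc01g111075.1, 578 ± 20.4 against 0.347 ± 0.113 CPM, 1640-fold), BRU1 (Solyc09g092520.3, 11.3-fold), glutamine synthetase (Solyc01g080280.3, 10.8-fold), an IAA-amino acid hydrolase (Solyc05g006220.3, 9.45-fold), glycolate oxidase (Solyc10g007600.3, 9.02-fold) and allene oxide synthase (Solyc04g079730.1, 8.78-fold). On the lower side were XYL2 (16-fold), a peroxidase (Solyc03g025380.3, 10.2-fold), a ring finger protein (Solyc03g117860.3, 9.93-fold), an exocyst component (Solyc10g081940.2, 8.76-fold), EME1B (Solyc04g051490.3, 8.67-fold) and a nucleoredoxin (Solyc05g005460.3, 8.29-fold). The glycolate oxidase values spread widely among the NOR-12 libraries, at 30.8 ± 25.4 CPM, and the log2 difference of 3.17 became 4.12 without NOR-12 replicate 1.

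By the edgeR test 8887 genes (42.8%) differed between the transgene lines, 4651 higher and 4236 lower in NOR-M138Q-18, 1796 of them by at least 2-fold (1040 higher, 756 lower), and 57.0% of genes had values that did not overlap (10% by chance). The share of higher genes, 52.3%, fell to 43.3% with library sizes alone (4044 higher and 5304 lower) and to 43.2% and 43.5% on FPKM. Adjusted over the list alone, the list counts were the same except for 5 higher and 9 lower in ethylene perception and response, 6 and 3 up to lycopene, 10 and 0 cuticle genes, 0 and 8 glycoalkaloid genes, 27 and 0 photosystem subunits, 27 and 9 heat shock proteins, 1 and 1 vascular markers, 3 and 5 histones, 14 and 121 ribosomal proteins, 4 and 5 auxin response genes and 20 and 13 ethylene-responsive factors. Signs differed for sugar genes (median 0.10, mean -0.02, test upward) and for methionine sulfoxide reductases (median 0.11, mean -0.11, test downward).

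**Figure D2:**
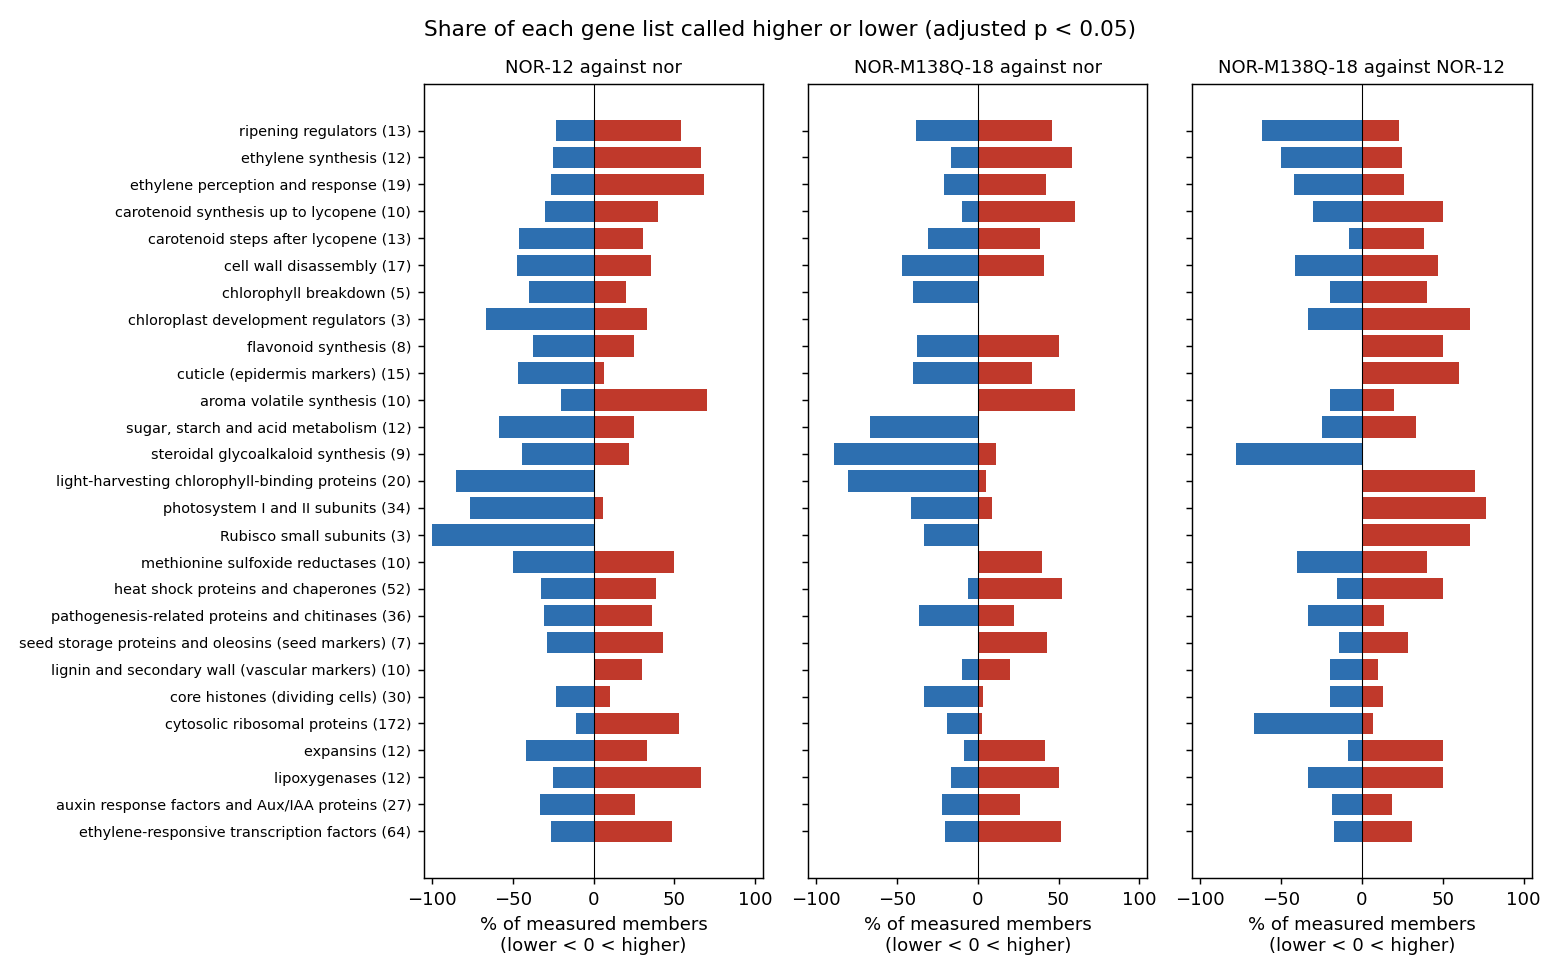
Percent of the measured members of each of the 27 gene lists called higher (to the right) or lower (to the left) in the 3 comparisons. In NOR-12 against nor, 26 of 34 photosystem subunits, 17 of 20 light-harvesting proteins and 3 of 3 Rubisco small subunits were lower. In NOR-M138Q-18 against NOR-12, 26, 14 and 2 of the same lists were higher.

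Both transgene lines moved 5966 genes in the same direction against nor, 3340 up and 2626 down, among them FUL1, PG2A, AADC1A and Z-ISO on the higher side and ACS4, PE1, GAD1 and light-harvesting genes on the lower side. Independent draws would give 1280 and 992. Both comparisons share the nor libraries. The covariance of the log2 changes across genes was 0.757, and 20 simulations of unchanged lines against these libraries gave a mean of 0.00706, lower by 0.75. Those lines were drawn around the observed nor means, so the sampling error of the shared controls cancelled in them. The simulation therefore cannot measure the covariance or overlap that shared controls add. Its mean covariance was subtracted only in computing the fraction of 0.66 used below, which is thus not corrected for shared controls. With 3 nor libraries the controls could not be divided into groups of 2 or more. Of the 6089 genes that rose in NOR-12, 3014 were lower in NOR-M138Q-18 than in NOR-12 by the direct test, 844 were higher and 2231 were not distinguished. Of the 5354 that fell, 3034 were less low or raised, 177 were lower still and 2143 were not distinguished. With both lines simulated at the NOR-12 means 20 times, at most 1 gene was called in any of these directions by the direct test. Choosing genes by their change in NOR-12 favours values nearer nor in the other line, so the balance of these counts is not read as a difference between the lines. Another 508 genes passed the test in both lines with opposite signs, EXP1, EBF2 and NAC4 among them. Of the 508, 24 differed from nor by at least 2-fold in each line.

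**Figure D3:**
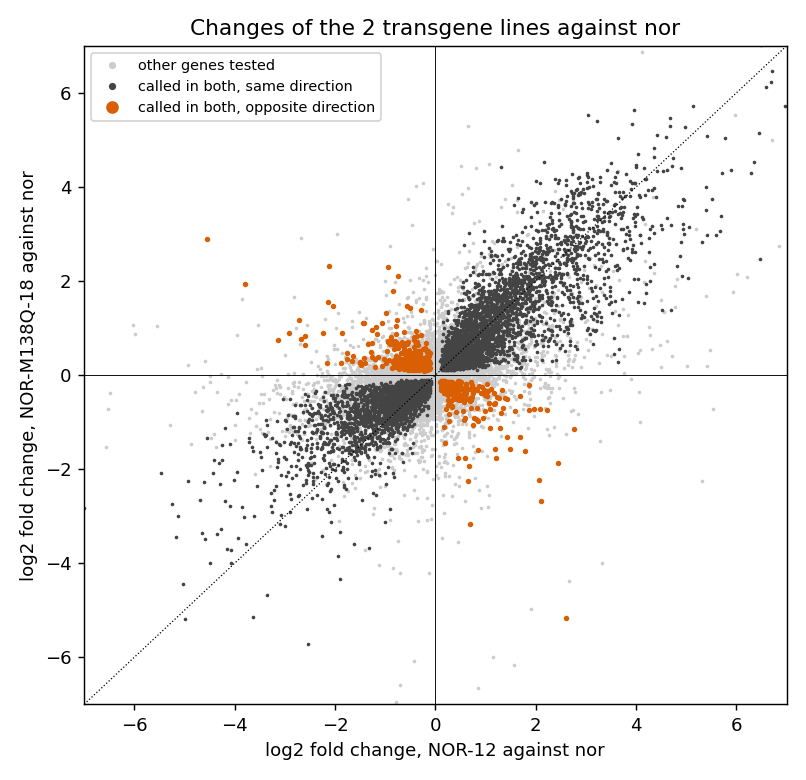
Log2 fold change against nor of each tested gene in NOR-12 (horizontal) and in NOR-M138Q-18 (vertical), with both axes limited to 7 log2 units on either side of 0 and 80 genes outside them. Genes called in the same direction in both lines number 5966 and those called in opposite directions 508.

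The authors' deposited tables list 3774 genes for NOR-12 against nor (2030 higher, 1744 lower) and 2482 for NOR-M138Q-18 against nor (1638 higher, 844 lower). Of these, 3604 and 2405 were tested here, and 99.1% and 98.1% were called in the same direction, with none in the opposite one. The authors' log2 fold changes from mean FPKM were 2.79 for ACS2, 2.00 for ACO1, 1.57 for E8 and 4.57 for AADC1A in NOR-12, and 1.70 for PG2A and 1.51 for LOXC in NOR-M138Q-18. Counts were made by gene model, and how reads shared by similar copies, such as those of chlorophyll-binding, Rubisco, histone and ribosomal protein genes, were assigned is not given in the sources used here.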

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

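The tests against a weaker form of one response and against a different share of epidermis were chosen only after the count of genes with opposite signs had been seen. Against nor, 508 genes passed the edgeR test in both transgene lines with opposite signs: 204 were higher in NOR-12 and lower in NOR-M138Q-18, and 304 were lower in NOR-12 and higher in NOR-M138Q-18. With an adjusted p under 0.01 the count was 263, and with a log2 fold change of at least 1 in each line it was 24.

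In 20 simulated sets NOR-M138Q-18 was given a fixed fraction (0.66) of the changes of genes called in NOR-12, and other genes were left unchanged. A positive fraction can give opposite calls only by error, so the sets count such errors, of which there were 0 to 2. The data gave 508. The simulation held only the spread between libraries of a line. It therefore argues against a fixed fraction with no other difference between the lines. A weaker response with small further differences between the lines was not simulated. For the number of opposite calls, the values argue against library scaling, since the lowest count under the other scalings was 515. Whether the same genes were called under each scaling was not counted. A different share of epidermis stays open for the genes higher in NOR-M138Q-18: of 15 cuticle genes 9 were higher and 0 lower in the direct test (median log2 0.29), whereas in NOR-M138Q-18 against nor 5 were higher and 6 lower (median log2 -0.23), and the direct median of the 304 genes, 0.75, decides nothing, since they were chosen by their changes. The substitution in NOR, the place of each insertion and the ripeness of the fruit at 55 days could each account for the pattern, and with 1 line per construct none of these was tested.

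The following named genes had opposite signs in the lines, with the direct log2 difference (NOR-M138Q-18 minus NOR-12) given for each. Among genes higher in NOR-12 than in nor and lower in NOR-M138Q-18, ethylene signalling gene EBF2 differed by -1.24, the NAC factor NAC4 by -0.79 and the glycoalkaloid gene GAME18 by -2.20. In the same direction the receptor-like kinase Solyc02g071800.3 differed by -2.91, the basic PR protein Solyc01g106620.2 by -1.42, the expansin EXP1 by -0.92 and the invertase TIV1 by -0.38. The ribosomal protein genes Solyc02g092080.2 and Solyc07g065170.3 differed by -0.94 and -0.44. Some of these lay close to nor in NOR-M138Q-18. The log2 changes of NOR-M138Q-18 against nor were -0.53 for EBF2, -0.19 for NAC4 and -1.76 for GAME18. They were -2.25 for Solyc02g071800.3, -0.71 for Solyc01g106620.2, -0.35 for EXP1 and -0.17 for TIV1. For Solyc02g092080.2 and Solyc07g065170.3 they were -0.21 and -0.14.

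Among genes lower in NOR-12 than in nor and higher in NOR-M138Q-18, BRU1 (Solyc09g092520.3) differed by 3.50, the IAA-amino acid hydrolase gene Solyc05g006220.3 by 3.24 and the ethylene-responsive factor gene Solyc09g089930.2 by 1.94. The expansin genes EXPA5 and Solyc09g010860.3 differed by 1.78 and 1.37. The heat shock protein genes Solyc03g082420.3 and Solyc03g007890.3 differed by 1.66 and 0.75. The flavonoid hydroxylase gene F3primeH differed by 0.84, the methionine sulfoxide reductase gene MSRA4 (Solyc03g093690.3) by 0.59, the carotenoid gene PDS by 0.53 and the wax gene CER6 by 0.37. The log2 changes of NOR-M138Q-18 against nor were 1.46 for BRU1, 2.3 for Solyc05g006220.3 and 1.18 for Solyc09g089930.2. They were 0.37 for EXPA5, 0.55 for Solyc09g010860.3, 0.26 for Solyc03g082420.3 and 0.41 for Solyc03g007890.3. F3primeH changed by 0.33, CER6 by 0.2, and MSRA4 and PDS by 0.16 each. For MSRA4, this higher value did not pass the test with library sizes alone, with upper-quartile scaling or on FPKM. Other increases this small could depend on the scaling too.

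For each comparison the 6 libraries allow 10 splits, which are too few for a share under 0.05. In fits of 6 libraries the real split called 10900 genes in NOR-12 against nor, 7808 in NOR-M138Q-18 against nor and 10004 in the direct comparison, the highest count of any other split was 0, and 1 split of the 10, the real one, gave as many genes. Every other split holds libraries of both lines on each side, so the difference between lines widens its spread. Counts near 0 were thereby set in advance, and no conclusion is drawn from the splits.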

How the results depend on the processing

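No test in this part was chosen after the results were seen. Counts of genes changed in each comparison, and of genes changed in the same direction in both lines, stayed within 1.5 times their values in each alternative except the fold minimum, and 0 calls turned to the opposite sign. The count of genes with opposite signs, 508, fell to 263 with a threshold of 0.01 and to 24 with the fold minimum, and lay between 383 and 618 in the others. With a log2 fold change of at least 1 the counts fell to 3691 in NOR-12 against nor, 2477 in NOR-M138Q-18 against nor, 1796 in the direct comparison and 1782 in the same direction in both lines. Called markers fell from 24, 23 and 21 of 27 to 8, 7 and 7, because most changes were smaller than 2-fold (median absolute log2 change of called genes 0.61, 0.56 and 0.45). With each library left out in turn the counts ran from 10326 to 11327, from 7082 to 8306, from 7580 to 9677 and from 5335 to 6070, and called markers from 23 to 25, from 22 to 25 and from 19 to 21. Gene lists called were 6, 8 and 11, with 5 to 9, 7 to 8 and 10 to 11 when a library was left out. On log2(FPKM + 0.1) the lists called in NOR-12 against nor fell to 3, and the cause was not tested. The fold minimum gives no value for lists, since camera uses no fold. Of 25 list calls 11 held in every setting and 14 ended in at least 1, and 12 others were gained in at least 1. Scaling set the balance of directions: in NOR-12 against nor the share of higher genes fell from 53.2% to 41.7% with upper-quartile factors, and in NOR-M138Q-18 against nor from 53.2% to 37.0% with library sizes alone and 35.4% with upper-quartile factors, and in the direct comparison from 52.3% to 43.3% with library sizes alone; in NOR-M138Q-18 against nor upper-quartile factors moved the median log2 change of all genes to -0.11. Of 396 results for named genes over 22 settings, 15 had no value with the filter of 1 CPM and 4 none with 6 libraries. Where a value was given 0 reversed, and apart from the fold minimum 359 kept their side of the threshold, 23 lost a call in at least 1 setting and 14 gained one. DESeq2 gave no p for 21 genes. Small changes can be missed, since 68.7% of simulated 1.5-fold changes were called. Smaller changes and other numbers of libraries were not simulated.

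The numbers of the replicates did not pair the libraries across lines: deviations from the line means correlated across genes between -0.01 and 0.03 for the 9 pairs of equal number, and 3 libraries correlated best with their own number in both other lines. With replicate number as a block 11232, 8060, 8686 and 5849 genes were called. For named genes 4 calls were lost with it, among them NOR in NOR-12 against nor (adjusted p = 0.0559, range over all alternatives 0.000697 to 0.146), and 1 was gained. The list of ethylene-responsive factors in NOR-12 against nor lost its call with the block (0.0624, range over all alternatives 0.019 to 0.124).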

Other observations

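The pathway tests, the genes named from among the most raised ones, the random comparison for copies of genes, and the condition on genes of at least 10 CPM were chosen only after the results were seen. Tested with camera over 119 pathways named in the deposited table, genes of plant-pathogen interaction gave an upward call in both transgene lines at the preset correlation. In NOR-M138Q-18 against nor 107 of 245 were higher and 40 lower (adjusted p = 2.76e-06; adjusted p = 0.0423 with an estimated correlation), and in NOR-12 against nor 121 were higher and 55 lower (adjusted p = 0.000435; adjusted p = 0.0926 with an estimated correlation). Phenylalanine metabolism, which feeds phenolics and volatiles, had 26 of 59 genes higher and 10 lower in NOR-M138Q-18 (adjusted p = 2.53e-05; adjusted p = 0.0423 with an estimated correlation) and 34 higher and 9 lower in NOR-12 (adjusted p = 7.35e-06; adjusted p = 0.072 with an estimated correlation). Against NOR-12, NOR-M138Q-18 had 28 of 52 genes of porphyrin and chlorophyll metabolism higher and 8 lower (adjusted p = 3.52e-06; adjusted p = 0.0465 with an estimated correlation). It had 39 of 56 proteasome genes lower and 2 higher (adjusted p = 4.05e-06; adjusted p = 0.431 with an estimated correlation).

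The following genes were picked from the most raised ones after their values were seen, and stand for no group. The fixed list of pathogenesis-related proteins was not called in NOR-12 against nor (13 of 36 higher, 11 lower, adjusted p = 0.132) or in NOR-M138Q-18 against nor (8 higher, 13 lower, adjusted p = 0.933). Solyc08g067340.3, described as a WRKY40 factor, stood at 4.75 CPM in nor, 117 CPM in NOR-12 and 48.3 CPM in NOR-M138Q-18. Solyc12g036390.2, with the symbol SARD1 in the table, stood at 0.613, 31.4 and 5.14 CPM in the same order. The neighbouring ubiquitin ligase genes Solyc01g007020.3 and Solyc01g007030.3, with the symbols PUB22 and PUB23, stood at 0.255 and 0.372 CPM in nor, 9.59 and 4.52 CPM in NOR-12, and 14.3 and 6.29 CPM in NOR-M138Q-18. The gene Solyc12g009220.2, described as a jasmonate ZIM-domain protein, stood at 3.24, 17.1 and 58.9 CPM.

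Genes with a change of 4 or more log2 units in at least 1 of the 3 comparisons, and at least 5 CPM in the highest line, numbered 96, with 53 higher in NOR-12 than in nor by 4 or more log2 units, 40 higher in NOR-M138Q-18, 12 lower in NOR-12 and 2 lower in NOR-M138Q-18; 13 changed that much the same way in both lines. Snakin-2 (Solyc01g111075.1) stood at 622, 0.347 and 578 CPM in nor, NOR-12 and NOR-M138Q-18, and the genes lower in NOR-M138Q-18, named after their values were seen, were Solyc01g059990.3, with no description, at 96.0, 243 and 0 CPM, and the aquaporin gene Solyc09g007770.2 at 5.62, 3.42 and 0.301 CPM. A single block of neighbouring genes, as around an insertion, is argued against as the cause of the whole, since 20 of the 96 had another member within 5 identifiers (upper bound 30.3%), although random sets had a median of 2. Reads counted on another copy could account for part of them and cannot be told apart from other causes: 26 of the 96 had a gene of the same symbol or a neighbour moving the opposite way by a similar amount, with an upper bound of 37.1%, and random genes in their place gave a median of 31. A change of the gene itself in one line, such as a deletion or an insertion, was not tested, since the counts hold no sequence.

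The NOR-12 libraries spread over 14.5 units of the first component, beside 1.8 for nor and 1.2 for NOR-M138Q-18. Library depth is argued against, as with all libraries thinned to the smallest total the spread was still 13.8. Libraries taken at different points between the lines, as with fruits of unequal ripeness, may account for some of it: the largest correlation across genes of a NOR-12 library's deviation with the difference of nor from NOR-M138Q-18 was 0.07, under the bound of 0.1 set beforehand as speaking against it. Counting noise in low genes weakens such correlations, and over the 11731 genes of at least 10 CPM, a condition added after the first value was seen, the correlations were 0.12, 0.00 and -0.11 in NOR-12 and within 0.05 of 0 in the other lines. This axis leaves out NOR-12, so it can miss a library nearer both other lines. NOR-12 replicates 1, 2 and 3 correlated with nor replicate 1 at 0.934, 0.926 and 0.922 (log2 CPM). With NOR-M138Q-18 replicate 1 the values were 0.964, 0.957 and 0.956. Their photosynthesis sums were 1242, 1122 and 1100 CPM. Unequal ripeness is therefore neither shown nor excluded.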
